A study of Homo sapiens with 30 samples.

How the data were processed

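RNA was measured by paired-end sequencing of stranded mRNA libraries (TruSeq kit, NextSeq instrument) from U2OS cells in 6 groups of 5, per the labels' protocols. CHIR99021 was given at 5 µM for 72 hours before transfection, and cells were transfected with 500 ng of plasmid for 48 hours. The labels call the 5 samples of a group biological replicates and do not say whether mock cells received an empty plasmid. The values used here are the whole-number gene counts that the authors deposited, 1 column per library, and they had not been normalised. The submitters' processing notes name STAR 2.6.1a, featureCounts, Subread, DESeq2 and the genome build hg19; the annotation release, the strand setting and whether reads or fragments were counted are not given in the sources used here. Each gene carries an Ensembl ID and a symbol as deposited, and no coordinates are printed because the reference at hand is of another build. With the strand setting not given, genes that overlap on opposite strands are uncertain, as are near-identical copies such as histone, RN7SL and ribosomal protein genes.

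The table held 57373 genes, of which 17378 had 0 counts in all 30 libraries. The default expression filter of edgeR over the 6 groups kept 18485 genes with 99.9% of the counts. The table held no mitochondrially encoded genes, so 24 of the 25 fixed gene lists could be used. Total counts were 15755842 to 29466652 per library, and the common biological coefficient of variation was 5.6%, so most genes were measured to within small differences. No pair of replicates differed by as little as sampling noise: the lowest chi-square per gene, over genes with at least 20 counts in the pair, was 1.39. Reads carry no molecular identifiers, so floors and counting intervals cover counting error only.

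Counts were scaled with trimmed means of M values and fitted in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, robust, all 30 libraries in 1 fit with a mean per group). A total of 12 comparisons were tested: 9 between pairs of groups and 3 interactions, each with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM, the usual count scaled to library depth, are computed on the scaled library sizes. A gene with 0 counts in 1 group is given a bound against a floor of 3 counts per library, and one with 1 to 3 counts a ratio with its 95% counting interval. Gene lists with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count of 2, preset correlation of 0.01), adjusted over the lists within each comparison; camera asks whether a list moves more than other genes. The lists for histone and ribosomal protein genes take every gene whose symbol has the family's prefix. FOXP2 levels were compared with two-sided exact permutation tests on log2 CPM. Overlaps of comparisons that share control libraries were set beside 5 simulated pairs of unchanged groups, and 10 splits of those controls.

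The groups, tests, gene lists, the rule for named genes and all alternatives except 2 were fixed before the data were examined. The rule names FOXP2, CTNNB1, AXIN2 and LEF1 everywhere; for pairs of groups, the genes with the largest log2 fold changes among those past the threshold with a mean of at least 1 CPM and no overlap between the libraries of the groups, 8 per direction in the 5 leading comparisons and 4 in the others; for interactions, the 5 with the smallest p in each direction; and up to 4 members of each list with a call. The alternatives were DESeq2 size factors, a replicate block, no filter, a mean of at least 1 CPM, FOXP2 left out of library sizes, a fit of the compared groups alone, DESeq2 1.42.0, each library left out in turn, and for lists an estimated correlation and fry. The 2 added after seeing the data were a test against a 2-fold change and a fit without CHIR replicate 1, dhelix replicate 5 and WT FOXP2 + CHIR replicate 4, which stood apart from their groups. The edgeR step was tested on simulated data for WT FOXP2 against mock with 17836 genes, where it recovered 54.0% of genes changed 1.2-fold, 86.0% at 1.5-fold, 98.0% at 2-fold and 100% at 4-fold, with 8 calls among 17636 unchanged genes. Only 200 genes were changed there, as many up as down, whereas 81.6% of genes passed in the real comparison. These rates therefore need not hold for the real data, least of all for small shifts. For interactions, splits of the libraries kept the effects of construct and CHIR by redrawing the residuals of log2 CPM, tested with limma on genes at 1 CPM or more in each group. Lower genes were left out because a first version that held them made calls in simulated data without an interaction. In 5 simulations each for the interaction of WT FOXP2 with CHIR, the real order made 0 calls without an interaction (12981 to 13015 genes in the step) and 211 to 221 calls with 200 genes given a 2-fold one (12979 to 13007 genes). No sample was left out of the comparisons, and 1 gene that the rule names is not reported here.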

Results

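The data are RNA-seq gene counts from U2OS, a human osteosarcoma cell line, in a design that crossed 3 constructs with a drug. Cells were mock-transfected, transfected with a plasmid for wild-type FOXP2 (WT FOXP2), or transfected with a plasmid for FOXP2 that lacks residues 264 to 272 (dhelix FOXP2). FOXP2 is a forkhead transcription factor known for its role in speech and language development. Each construct was studied without and with CHIR99021 (CHIR), an inhibitor of glycogen synthase kinase 3 that is widely used to stabilise β-catenin and so to activate Wnt signalling. The 6 groups held 5 biological replicates each, 30 libraries in all, with total counts of 15755842 to 29466652 per library. Of the 18485 genes tested, 9.6% of the variance lay between replicates of 1 group. The first principal component held 52.7% of the variance, the second 23.0% and the third 11.5%. Unless stated otherwise, a value after ± is the standard error of a log2 fold change or the SD of a level in CPM, n = 5 libraries per group, and a gene "rose" or "fell" where edgeR's quasi-likelihood test gave an adjusted p under 0.05.

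FOXP2 (ENSG00000128573) was close to absent in the groups without a FOXP2 plasmid and abundant in every library of the groups with one. Its level was 0.898 ± 0.284 CPM in mock and 0.504 ± 0.462 CPM with CHIR alone, 7076 ± 779 CPM with WT FOXP2 and 5319 ± 641 CPM with dhelix FOXP2 (n = 5 each). With CHIR the groups with a FOXP2 plasmid held more of it, 15299 ± 983 CPM with WT FOXP2 and 13481 ± 917 CPM with dhelix FOXP2 (n = 5 each), so that FOXP2 took 1.55% and 1.36% of all counts. The dhelix level was 0.751 times the WT level without CHIR (two-sided exact permutation p = 0.0159) and 0.881 times with CHIR (two-sided exact permutation p = 0.0159). CHIR went with 2.17 times the FOXP2 level in WT FOXP2 cells and 2.54 times in dhelix FOXP2 cells (two-sided exact permutation p = 0.00794 each, the smallest that 5 against 5 can give). These counts add plasmid and endogenous transcripts, so the groups differ in construct and also in the amount of FOXP2 RNA.

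**Figure D1:**
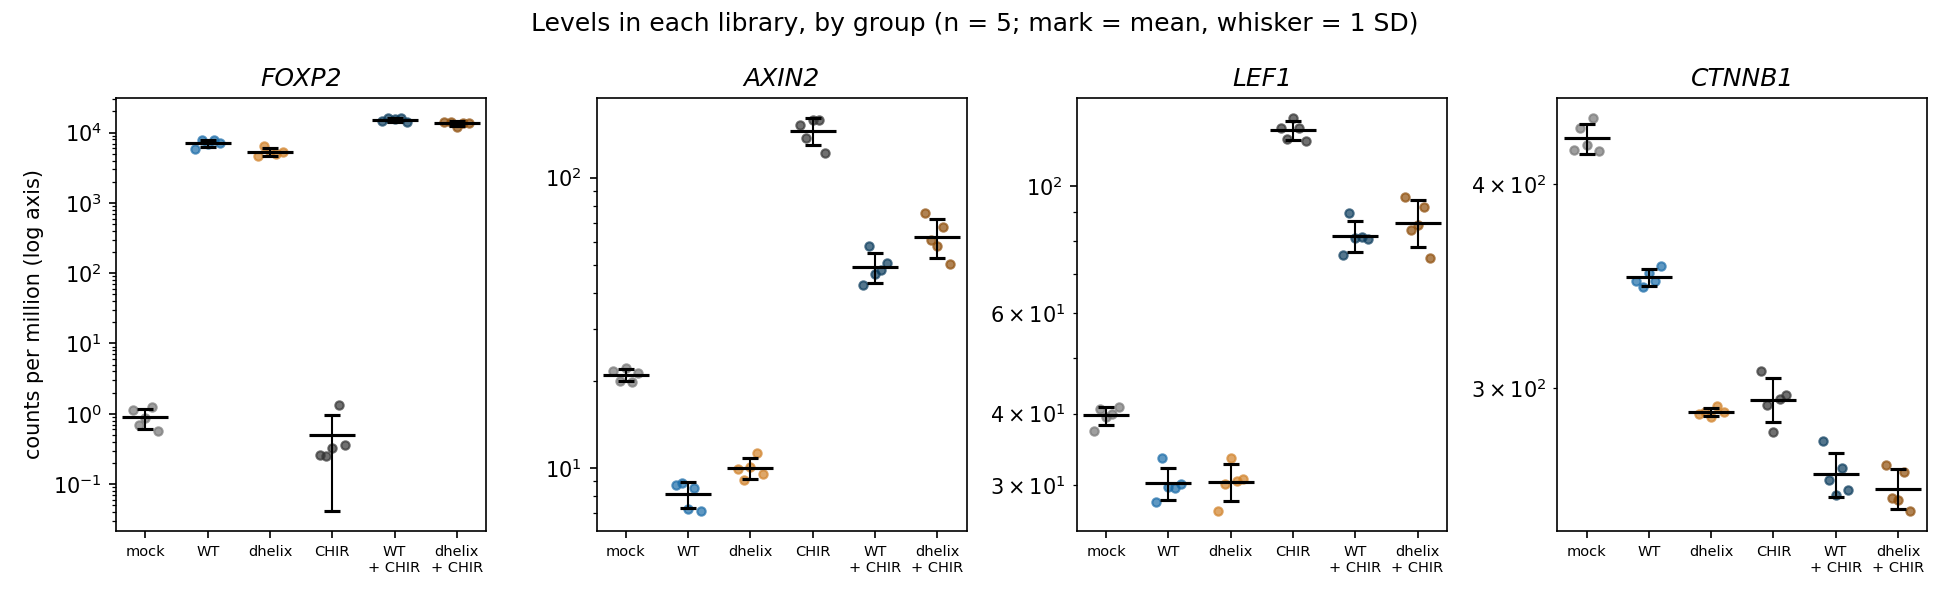
Levels in CPM (log axis) of FOXP2, AXIN2, LEF1 and CTNNB1 in each of the 30 libraries, by group; points are libraries, horizontal marks are group means and whiskers 1 SD (n = 5). FOXP2 separates the groups with a FOXP2 plasmid from those without, and AXIN2 is highest with CHIR alone, at 145 ± 15.7 CPM.

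CHIR alone, compared with mock, raised the 2 Wnt markers AXIN2 and LEF1. Most extracellular matrix and mitotic genes fell, list calls that were lost with an estimated correlation (adjusted p = 0.088 and adjusted p = 0.10). AXIN2 (ENSG00000168646), a feedback inhibitor and direct target of Wnt/β-catenin signalling, rose by 2.79 ± 0.09 on the log2 scale, from 21.0 to 145 CPM, and LEF1 (ENSG00000138795), the DNA-binding partner of β-catenin, by 1.65 ± 0.06, from 39.7 to 125 CPM. CTNNB1 (ENSG00000168036), which encodes β-catenin itself, fell by 0.53 ± 0.03, from 427 to 295 CPM. The genes that rose most included MUCL1, a small mucin-like gene, at least 178-fold, the chemokine CXCL6, at least 110-fold, and GZMB, the cytotoxic protease granzyme B, by a ratio of 4179 (counting interval 1430 to 20266). Those that fell most included MYOCD, a coactivator of smooth muscle genes (-9.10 ± 0.18), the forkhead gene FOXS1 (-8.75 ± 0.21), GALNT15 (-8.24 ± 0.25) and the serotonin receptor HTR2A (-7.08 ± 0.26). These genes were near 0 in 1 group, so single libraries moved them: without CHIR replicate 5 FOXS1 was at -10.66 and HTR2A at -7.99, and without mock replicate 4 GZMB was at 12.74.

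Among the fixed lists, 37 of 42 extracellular matrix genes fell with CHIR and 4 rose, the same counts as adjusted over the list alone, with a median log2 fold change of -1.22 (camera adjusted p = 1.2e-10, adjusted p = 0.088 with an estimated correlation). THBS1 (thrombospondin-1) went from 897 to 64.4 CPM (-3.80 ± 0.04) and LAMA4, a laminin chain, fell by 3.50 ± 0.07. Of 35 mitotic genes 33 fell and 1 rose, 34 and 1 adjusted over the list alone. The median was -0.37 (camera adjusted p = 2.7e-08, adjusted p = 0.10 with an estimated correlation). KIF20A was at -1.17 ± 0.04 and the proliferation marker MKI67 at -0.84 ± 0.03. Of 43 DNA replication genes 27 fell and 9 rose, the same adjusted over the list alone. The median was -0.28 (camera adjusted p = 0.00057, adjusted p = 0.088 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, was at -1.43 ± 0.04. Of 31 interferon-stimulated genes 24 fell and 2 rose, the same adjusted over the list alone. The median was -0.85 (camera adjusted p = 3.7e-05, adjusted p = 0.088 with an estimated correlation). OASL was at -5.66 ± 0.13. Ribosomal protein genes went the other way, 79 of 83 up and 1 down, the same adjusted over the list alone. The median was 0.53 (camera adjusted p = 3.2e-15, adjusted p = 0.10 with an estimated correlation).

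The Wnt target list did not move one way with CHIR: 15 of its 29 genes rose and 11 fell, the same adjusted over the list alone. The median was 0.27 (camera adjusted p = 0.65). Among its members, EPHB3 was at -4.08 ± 0.09 and PTCH1 at -3.52 ± 0.05. Of 42 Wnt pathway components 15 rose and 24 fell, the same adjusted over the list alone. The median was -0.14 (camera adjusted p = 0.075). TGF-β, SMAD and YAP targets fell in 18 of 30 cases and rose in 10, the same adjusted over the list alone. The median was -0.51 (camera adjusted p = 0.028, adjusted p = 0.10 with an estimated correlation). CTGF went from 185 to 19.5 CPM (-3.24 ± 0.06). FOXO targets fell in 18 of 25 and rose in 5, 20 and 5 adjusted over the list alone. The median was -0.53 (camera adjusted p = 0.0051, adjusted p = 0.10 with an estimated correlation). Lysosome and autophagy genes rose in 23 of 35 and fell in 11, the same adjusted over the list alone. The median was 0.39 (camera adjusted p = 0.042, adjusted p = 0.28 with an estimated correlation). Cholesterol synthesis genes fell in 13 of 24 and rose in 3, the same adjusted over the list alone. The median was -0.19 (camera adjusted p = 0.028, adjusted p = 0.088 with an estimated correlation). Osteoblast lineage genes went both ways, 6 up and 8 down of 18, the same adjusted over the list alone. The median was -0.14 (camera adjusted p = 0.50). The growth factor gene BMP2 was at 2.84 ± 0.07 and the collagen gene COL1A1 at -2.35 ± 0.11.

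In all, 13695 genes passed the threshold with CHIR, 7169 up and 6526 down, of which 1664 and 2395 changed at least 2-fold, and 2828 passed a test against a 2-fold change. CHIR replicate 1 stood apart: its mean chi-square per gene against the other 4 CHIR libraries was 28.6, against 7.41 to 10.8 for the others. Its extracellular matrix genes lay at a median of -0.28 on the log2 scale against the 4 others and its mitotic genes at 0.18. FOXP2 itself was at -0.88 ± 0.43 (adjusted p = 0.068) and passed the threshold without CHIR replicate 4 (-1.59, adjusted p = 0.0015) or mock replicate 5 (adjusted p = 0.048), with no filter on low counts, with a mean of at least 1 CPM required and in DESeq2 (adjusted p of 0.0013 to 0.36 over all alternatives).

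WT FOXP2, compared with mock, lowered the Wnt markers AXIN2 and LEF1. The labels do not say whether cells of the mock and CHIR groups received an empty plasmid. Wherever groups with a FOXP2 plasmid are compared with these, effects of FOXP2 and of plasmid DNA cannot be told apart. Most cytokine, ER stress, heat shock and immediate early genes rose, list calls that were lost with an estimated correlation (adjusted p = 0.053 for the first 3 lists and adjusted p = 0.12 for the last). AXIN2 fell by 1.38 ± 0.11, from 21.0 to 8.11 CPM, LEF1 by 0.39 ± 0.06 and CTNNB1 by 0.28 ± 0.03. The secreted collagenase MMP1 rose at least 164-fold, the lysophosphatidic acid receptor gene LPAR6 at least 153-fold, and the cytokine IL24 from 0.202 to 104 CPM (8.99 ± 0.15). PRND, which encodes a prion-like protein, fell at least 95.0-fold and KANK4 at least 42.6-fold, HTR2A fell by a ratio of 858 (counting interval 154 to 33898), and SOSTDC1, a secreted Wnt and BMP antagonist, by a ratio of 504 (172 to 2442). Without WT replicate 2, HTR2A was at -10.44 and SOSTDC1 at -9.66 on the log2 scale.

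Of 21 cytokine and NF-κB response genes 16 rose with WT FOXP2 and 4 fell, the same adjusted over the list alone. The median was 2.66 (camera adjusted p = 1.6e-05, adjusted p = 0.053 with an estimated correlation). IL8, a neutrophil chemoattractant, went from 0.373 to 87.5 CPM (7.86 ± 0.13), and TRAF1 was at 5.87 ± 0.09. Immediate early and MAPK feedback genes rose in 21 of 28 and fell in 6, the same adjusted over the list alone. The median was 1.15 (camera adjusted p = 5.3e-05, adjusted p = 0.12 with an estimated correlation). FOSB, a subunit of AP-1, was at 4.64 ± 0.15. ER stress and ATF4 genes rose in 27 of 36 and fell in 7, the same adjusted over the list alone. The median was 1.08 (camera adjusted p = 3.7e-05, adjusted p = 0.053 with an estimated correlation). DDIT3, a transcription factor of the unfolded protein response, was at 2.70 ± 0.05. Heat shock genes rose in 15 of 17 and fell in 2, the same adjusted over the list alone. The median was 1.08 (camera adjusted p = 3.7e-05, adjusted p = 0.053 with an estimated correlation). The chaperone gene HSPA8 was at 1.47 ± 0.03. Hypoxia and glycolysis genes rose in 20 of 30 and fell in 8, the same adjusted over the list alone. The median was 0.47 (camera adjusted p = 0.032, adjusted p = 0.28 with an estimated correlation). The hexokinase gene HK2 was at 3.41 ± 0.05.

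Most matrix and Wnt target genes fell with WT FOXP2, list calls that were lost with an estimated correlation (adjusted p = 0.062 and adjusted p = 0.053). Of 42 extracellular matrix genes 38 fell and 3 rose, the same adjusted over the list alone. The median was -1.36 (camera adjusted p = 2.2e-09, adjusted p = 0.062 with an estimated correlation). The collagen gene COL3A1 was at -4.07 ± 0.08. Of 29 Wnt target genes 23 fell and 5 rose, the same adjusted over the list alone. The median was -1.38 (camera adjusted p = 0.00015, adjusted p = 0.053 with an estimated correlation). RNF43, a feedback ubiquitin ligase that removes Wnt receptors, went from 56.1 to 1.17 CPM (-5.59 ± 0.20). Interferon-stimulated genes fell in 27 of 31 and rose in 4, the same adjusted over the list alone. The median was -1.38 (camera adjusted p = 3.7e-05, adjusted p = 0.062 with an estimated correlation). Axon guidance and neuronal genes fell in 21 of 40 and rose in 8, the same adjusted over the list alone. The median was -0.52 (camera adjusted p = 0.032, adjusted p = 0.053 with an estimated correlation). The netrin receptor gene UNC5C was at -5.67 ± 0.14 and MAP2 at -5.03 ± 0.12, while the ephrin receptor gene EPHB1 was at 3.84 ± 0.06. Genes described as FOXP2 targets fell in 12 of 19 and rose in 6, the same adjusted over the list alone. The median was -0.58 (camera adjusted p = 0.36). CNTNAP2, a gene that FOXP2 is known to repress in neurons, was at -5.56 ± 0.18 and the related forkhead gene FOXP1 at -2.52 ± 0.07. Of 13 epithelial markers 8 fell and 3 rose, the same adjusted over the list alone. The median was -0.59 (camera adjusted p = 0.17). The keratin gene KRT14 was at -6.63 ± 0.12. Of 7 blood cell markers 5 rose and 2 fell, the same adjusted over the list alone, and the list just missed the threshold (median 1.85, camera adjusted p = 0.05). p53 targets went both ways, 9 up and 16 down of 30, the same adjusted over the list alone. The median was -0.18 (camera adjusted p = 0.30).

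In all, 15083 genes passed the threshold with WT FOXP2, 7384 up and 7699 down, of which 2480 and 3553 changed at least 2-fold, and 4670 passed the test against a 2-fold change. The 5 WT FOXP2 and 5 mock libraries did not overlap for 13498 of the 18485 genes tested (73.0%), where chance gives 0.79%.

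dhelix FOXP2, compared with mock, moved several of the lists that WT FOXP2 moved. AXIN2 fell by 1.07 ± 0.10, LEF1 by 0.39 ± 0.06 and CTNNB1 by 0.56 ± 0.03, from 427 to 290 CPM. LPAR6 rose at least 128-fold and MMP1 at least 121-fold, MAL, a myelin and lymphocyte membrane protein gene, by a ratio of 3747 (counting interval 673 to 148017), or by 12.52 on the log2 scale without mock replicate 2. Cytokine genes rose in 16 of 21 and fell in 3, the same adjusted over the list alone. The median was 2.18 (camera adjusted p = 7.9e-06). Heat shock genes rose in 15 of 17 and fell in 2 (median 0.94, camera adjusted p = 1.4e-05), and ER stress genes rose in 27 of 36 and fell in 6 (median 0.92, camera adjusted p = 1.4e-05). Wnt targets fell in 22 of 29 and rose in 5 (median -1.19, camera adjusted p = 0.00012) and axon guidance genes fell in 23 of 40 and rose in 10 (median -0.37, camera adjusted p = 0.018). Each of these 4 pairs of counts was the same adjusted over the list alone. The 5 lists stayed past the threshold with an estimated correlation (adjusted p of 0.041 for cytokine, heat shock and axon guidance genes and 0.045 for ER stress and Wnt target genes). Of 7 blood cell markers 5 rose and 2 fell, the same adjusted over the list alone. The median was 2.64 (camera adjusted p = 0.017, adjusted p = 0.045 with an estimated correlation). The blood markers that rose stayed low in level, ITGAM from 0.123 to 5.59 CPM and CD3D from 0.0688 to 5.49 CPM. A total of 13 of the 24 lists passed here, and only the 6 above kept their call with an estimated correlation. Among the others, extracellular matrix genes fell in 38 of 42 and rose in 3 (median -1.08, camera adjusted p = 6.6e-09, adjusted p = 0.06 with an estimated correlation). Interferon-stimulated genes fell in 25 of 31 and rose in 2 (median -1.33, camera adjusted p = 1.5e-05, adjusted p = 0.051 with an estimated correlation).

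In all, 14880 genes passed the threshold with dhelix FOXP2, 7328 up and 7552 down, of which 2370 and 3080 changed at least 2-fold and 4123 passed the test against a 2-fold change. Of these calls 13594 were shared with WT FOXP2 in the same direction and 89 in the opposite direction, FOXP2 left out. Independent lists of these sizes would share 2927 of the 6677 genes that rose with both and 3146 of the 6917 that fell with both. Because both comparisons use the mock libraries, the correlation across genes of 0.96 has a value of 0.52 in simulated groups with no effect, and the covariance of 2.10 one of 0.0080, with 0 shared calls. With the mock libraries split between the comparisons, 12460 to 12632 genes were shared, at a covariance of 2.11 to 2.12. Such splits bear on the shared libraries only. A response to plasmid DNA, if mock cells had none, would be shared as well and was not tested.

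dhelix FOXP2 was then set against WT FOXP2 directly. The groups differ in the deleted residues and also in the FOXP2 transcript, which with dhelix FOXP2 was at 0.751 times the WT level. This comparison by itself cannot tell the 2 apart. The secreted mucin gene MUC5AC was higher with dhelix FOXP2, at 40.2 against 5.14 CPM (2.95 ± 0.10), as was MAL, at 35.6 against 5.09 CPM (2.80 ± 0.09). The chemokine receptor gene CCR4 (-2.34 ± 0.17), the dynein gene DNAH3 (-2.24 ± 0.13), the immediate early gene EGR4 (-2.08 ± 0.13) and the autophagy gene IRGM (-2.07 ± 0.12) were lower. CTNNB1 was lower with dhelix FOXP2, at 290 against 351 CPM (-0.27 ± 0.03), LEF1 did not differ (0.01 ± 0.06, adjusted p = 0.95), and AXIN2 was slightly higher (0.30 ± 0.12, adjusted p = 0.046).

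Immediate early genes were lower with dhelix FOXP2 in 21 of 28 cases and higher in 1, the same adjusted over the list alone. The median was -0.23 (camera adjusted p = 7.3e-09, adjusted p = 0.088 with an estimated correlation). EGR1 was at -0.71 ± 0.07 and FOSL1 at -0.57 ± 0.06. Cytokine genes were lower in 13 of 21 and higher in 2, 13 and 3 adjusted over the list alone. The median was -0.27 (camera adjusted p = 0.0059, adjusted p = 0.23 with an estimated correlation). IL8 was at -0.94 ± 0.07 and IL1A, which encodes interleukin-1 alpha, at -1.18 ± 0.11. Extracellular matrix genes were higher in 21 of 42 and lower in 6, 22 and 7 adjusted over the list alone. The median was 0.21 (camera adjusted p = 0.0083, adjusted p = 0.45 with an estimated correlation). The basement membrane gene NID1 was at 0.81 ± 0.04. Ribosomal protein genes were higher in 62 of 83 and lower in 2, 66 and 3 adjusted over the list alone. The median was 0.17 (camera adjusted p = 1.3e-13, adjusted p = 0.23 with an estimated correlation). Cholesterol synthesis genes were higher in 10 of 24 and lower in 2, the same adjusted over the list alone. The median was 0.09 (camera adjusted p = 0.039, adjusted p = 0.088 with an estimated correlation). INSIG1, a brake on sterol synthesis, was at 50.4 against 19.7 CPM (1.36 ± 0.06).

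In all, 6588 genes passed the threshold, 3123 higher and 3465 lower with dhelix FOXP2, of which 345 and 129 differed at least 2-fold and 75 passed the test against a 2-fold change. With no filter on low counts, 62.9% of the calls were higher with dhelix FOXP2, against 47.4% with it. The noncoding RNAs RN7SL2 (3.84 ± 0.85) and RN7SL1 (3.06 ± 0.86), near-identical copies whose reads cannot be told apart with certainty, were highest in dhelix replicate 5, RN7SL2 at 89.0 CPM against 7.78 to 21.9 in the other dhelix libraries and RN7SL1 at 173 against 9.59 to 20.2. That library held 6636 CPM of 7 noncoding RNAs (RN7SL1, RN7SL2, RN7SK, RMRP, RPPH1, RNA18S5 and RNA28S5) against 292 to 511 in the other dhelix libraries. Without it RN7SL2 was at 2.82 (adjusted p = 0.0049) and RN7SL1 at 1.40 (adjusted p = 0.12, the highest over its alternatives, of which a fit of these 2 groups alone gave 0.068). The AXIN2 call was lost without WT replicate 3, 4 or 5 and without dhelix replicate 1, 3 or 4, where its adjusted p was 0.053 to 0.13, and without the 3 libraries that stood apart (0.14, the highest over its alternatives).

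With CHIR in both groups, WT FOXP2 again lowered Wnt markers and raised cytokines, and histone transcripts were higher, as was the sum of the 7 noncoding RNAs. Compared with CHIR alone, AXIN2 fell by 1.56 ± 0.08, from 145 to 49.2 CPM, LEF1 by 0.61 ± 0.05 and CTNNB1 by 0.15 ± 0.03. MLC1, an astrocyte membrane protein gene, rose from 0.0672 to 102 CPM (10.44 ± 0.16), MUC5AC from 0.0494 to 53.1 CPM (10.03 ± 0.22), CSF3, which encodes granulocyte colony-stimulating factor, at least 32.2-fold, and LPAR6 by a ratio of 6840 (counting interval 1228 to 270157). Without CHIR replicate 2 MUC5AC was at 10.64, and without CHIR replicate 4 LPAR6 was at 13.64. The calcium-binding protein gene PVALB fell from 31.7 to 0.283 CPM (-6.75 ± 0.18), and the desmosome gene DSC1 (-7.13 ± 0.26), KANK4 (-7.17 ± 0.31) and FILIP1 (-6.33 ± 0.18) fell as well.

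Cytokine and NF-κB genes rose in 20 of 21 and fell in none, the same adjusted over the list alone. The median was 2.19 (camera adjusted p = 9.3e-09, adjusted p = 0.0046 with an estimated correlation). IL6 was higher by a ratio of 96.7 (counting interval 33.1 to 469) and IL8 was at 4.30 ± 0.09. Of 28 replication-dependent histone genes 24 rose and 0 fell, the same adjusted over the list alone. The median was 1.15 (camera adjusted p = 5.3e-06, adjusted p = 0.0046 with an estimated correlation). HIST1H4H went from 8.74 to 60.6 CPM (2.79 ± 0.06). Histone transcripts normally lack a poly(A) tail and are near-identical between copies, so single copies are uncertain. In sum the 7 noncoding RNAs were also higher, at 492 to 4603 CPM with WT FOXP2 + CHIR against 333 to 437 CPM with CHIR. Carry-over of RNA without a tail was not tested for this histone rise. Mitotic genes fell in 29 of 35 and rose in 4, the same adjusted over the list alone. The median was -0.50 (camera adjusted p = 8.7e-06, adjusted p = 0.20 with an estimated correlation). TOP2A, a topoisomerase gene, was at -1.19 ± 0.05. In CHIR replicate 1, a control library here, the mitotic list lay at 0.18 against the 4 other CHIR libraries (these at -0.10 to 0.02), TOP2A was at 1061 CPM against 770 to 827, and the matrix, cytokine and immediate early lists lay at -0.28, -0.14 and -0.13. Ribosomal protein genes fell in 67 of 83 and rose in 7, the same adjusted over the list alone. The median was -0.37 (camera adjusted p = 4.8e-08, adjusted p = 0.20 with an estimated correlation). Immediate early genes rose in 20 of 28 and fell in 4, the same adjusted over the list alone. The median was 0.70 (camera adjusted p = 0.00079, adjusted p = 0.20 with an estimated correlation). FOSB was at 7.16 ± 0.19. Heat shock genes rose in 14 of 17 and fell in 1, the same adjusted over the list alone. The median was 0.52 (camera adjusted p = 4.9e-05, adjusted p = 0.052 with an estimated correlation). HSPA6 was at 4.27 ± 0.22. Extracellular matrix genes fell in 28 of 42 and rose in 8, 29 and 8 adjusted over the list alone. The median was -0.45 (camera adjusted p = 0.0017, adjusted p = 0.25 with an estimated correlation). Of 7 blood cell markers 5 rose and 2 fell, the same adjusted over the list alone. The median was 2.00 (camera adjusted p = 0.041, adjusted p = 0.11 with an estimated correlation). Of 8 endothelial markers 6 rose and none fell, the same adjusted over the list alone. The median was 1.23 (camera adjusted p = 0.05, just past the threshold, adjusted p = 0.20 with an estimated correlation), and in CHIR replicate 1 this list lay at a median of -0.61 against the 4 other CHIR libraries, and in WT FOXP2 + CHIR replicate 4 at -0.17 against the 4 others of its group.

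In all, 14484 genes passed the threshold, 7058 up and 7426 down, of which 2553 and 2214 changed at least 2-fold and 3328 passed the test against a 2-fold change. CHIR replicate 1, which stood apart, is among the control libraries here, and WT FOXP2 + CHIR replicate 4 held 4603 CPM of the 7 noncoding RNAs against 492 to 691 in the others of its group. In that library interferon-stimulated genes lay at a median of -0.13 against those 4. Between WT FOXP2 without and with CHIR, comparisons that share no library, 9968 calls had the same direction and 2303 the opposite (correlation across genes 0.64; independent lists would share 2819 of the 4935 that rose in both and 3093 of the 5033 that fell in both).

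dhelix FOXP2 with CHIR, compared with CHIR alone, raised all 21 cytokine and NF-κB genes, the same adjusted over the list alone. The median was 2.07 (camera adjusted p = 2.0e-10, adjusted p = 0.0024 with an estimated correlation). TRAF1 was at 4.76 ± 0.08 and IL8 at 4.51 ± 0.09. AXIN2 fell by 1.21 ± 0.08, from 145 to 62.4 CPM, LEF1 by 0.53 ± 0.05 and CTNNB1 by 0.18 ± 0.03. MUC5AC rose from 0.0494 to 151 CPM (11.54 ± 0.19) and MAL by a ratio of 7838 (counting interval 1407 to 309590), and DSC1 fell by 5.79 ± 0.23. Without CHIR replicate 2 MUC5AC was at 12.15, and without CHIR replicate 5 MAL was at 13.84. Heat shock genes rose in 14 of 17 and fell in 1, the same adjusted over the list alone. The median was 0.58 (camera adjusted p = 7.5e-06, adjusted p = 0.036 with an estimated correlation). p53 targets fell in 21 of 30 and rose in 8, the same adjusted over the list alone. The median was -0.41 (camera adjusted p = 0.015, adjusted p = 0.036 with an estimated correlation). The p53-induced gene TP53INP1 was at -1.64 ± 0.07. Of 8 endothelial markers 7 rose and 0 fell, the same adjusted over the list alone. The median was 1.25 (camera adjusted p = 0.018, adjusted p = 0.14 with an estimated correlation). VWF went from 2.71 to 41.2 CPM (3.93 ± 0.12) and TIE1 from 0.407 to 5.59 CPM (3.78 ± 0.19). In CHIR replicate 1 this list lay at a median of -0.61 against the 4 other CHIR libraries, and the cytokine list at -0.14. Of 7 blood cell markers 5 rose and 2 fell, the same adjusted over the list alone. The median was 2.88 (camera adjusted p = 0.019, adjusted p = 0.061 with an estimated correlation). Histone genes rose in 19 of 28 and fell in 3, the same adjusted over the list alone. The median was 0.71, or 0.51 with undetected genes at their bound (camera adjusted p = 0.0028, adjusted p = 0.061 with an estimated correlation).

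In all, 14031 genes passed the threshold, 6842 up and 7189 down, of which 2354 and 1704 changed at least 2-fold and 2688 passed the test against a 2-fold change. WT and dhelix FOXP2 shared 12823 calls in the same direction with CHIR and 76 in the opposite (2612 of the 6229 that rose and 2888 of the 6594 that fell from independent lists), at a correlation across genes of 0.96 and a covariance of 1.64. Simulated groups with no effect gave 0.49 and 0.0086 with 0 shared calls, and with the CHIR libraries split 11220 to 11482 genes were shared, at a covariance of 1.65 to 1.67. A shared response to plasmid DNA was not tested here either.

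Setting dhelix FOXP2 + CHIR against WT FOXP2 + CHIR, histone genes were lower with dhelix FOXP2 in 17 of 28 cases and higher in none, 20 and 0 adjusted over the list alone. Here too the FOXP2 transcript differed, at 0.881 times the WT level, which this comparison by itself cannot tell apart from the deletion. The median was -0.60 (camera adjusted p = 3.6e-12, adjusted p = 6e-05 with an estimated correlation). HIST1H3D was at -1.36 ± 0.11. Summed over all histone genes the level was 844 ± 9.67 CPM with dhelix FOXP2 and 923 ± 22.1 CPM with WT FOXP2, a ratio of 1.09. Abundant RNAs without a poly(A) tail (RN7SL1, RN7SL2, RN7SK, RMRP, RPPH1 and 2 ribosomal RNAs) were in sum also lower with dhelix FOXP2, at 449 ± 44.7 CPM (n = 5) against 574 ± 85.9 CPM (n = 4, without replicate 4; two-sided exact permutation p = 0.0159). DNA replication genes were higher in 24 of 43 and lower in 3, 27 and 3 adjusted over the list alone. The median was 0.12 (camera adjusted p = 7.6e-07, adjusted p = 0.0048 with an estimated correlation). GINS2, part of the replicative helicase, was at 0.40 ± 0.05. Axon guidance genes were higher in 20 of 40 and lower in 3, 22 and 3 adjusted over the list alone. The median was 0.23 (camera adjusted p = 0.0028, adjusted p = 0.0048 with an estimated correlation). The cystatin genes CST1 (2.15 ± 0.29) and CST5 (1.78 ± 0.24), FILIP1 (2.06 ± 0.29) and the mucin gene MUC5B (1.82 ± 0.16) were higher, and IRGM (-1.83 ± 0.12), CCR4 (-1.74 ± 0.17) and ARL14 (-1.51 ± 0.14) were lower. AXIN2 was higher, at 62.4 against 49.2 CPM (0.35 ± 0.08, adjusted p = 0.0018), while LEF1 (0.08 ± 0.05, adjusted p = 0.28) and CTNNB1 (-0.03 ± 0.03, adjusted p = 0.46) did not pass.

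Of 29 Wnt target genes 13 were higher with dhelix FOXP2 and 4 lower, the same adjusted over the list alone. The median was 0.17 (camera adjusted p = 0.0054, adjusted p = 0.11 with an estimated correlation). WISP1 was at 1.66 ± 0.15. Extracellular matrix genes were higher in 26 of 42 and lower in 3, 33 and 3 adjusted over the list alone. The median was 0.30 (camera adjusted p = 3.3e-11, adjusted p = 0.065 with an estimated correlation). COL6A1 was at 0.74 ± 0.08. Interferon-stimulated genes were higher in 14 of 31 and lower in 2, 16 and 2 adjusted over the list alone. The median was 0.28 (camera adjusted p = 0.00022, adjusted p = 0.11 with an estimated correlation). In WT FOXP2 + CHIR replicate 4, a library with much noncoding RNA, this list lay at -0.13 against the 4 others of its group (these at -0.05 to 0.12), the matrix list at -0.05, the Wnt target list at -0.05 and the axon guidance list at -0.06. Immediate early genes were lower in 15 of 28 and higher in 0, 16 and 1 adjusted over the list alone. The median was -0.18 (camera adjusted p = 1.7e-05, adjusted p = 0.11 with an estimated correlation). ATF3 was at -0.53 ± 0.04. In all, 5655 genes passed the threshold, 3077 higher and 2578 lower, of which 283 and 116 differed at least 2-fold and 23 passed the test against a 2-fold change. The dhelix minus WT differences without and with CHIR, which share no library, had the same direction for 2812 calls and the opposite for 227 (1385 higher in both against 520 from independent lists, 1427 lower in both against 483). The AXIN2 call was lost in a fit of these 2 groups alone (adjusted p = 0.063, the highest over its alternatives).

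CHIR in WT FOXP2 cells, against WT FOXP2 alone, lowered all 35 mitotic genes, the same adjusted over the list alone. The median was -0.69 (camera adjusted p = 4.5e-21, adjusted p = 0.011 with an estimated correlation). CKAP2L was at -1.46 ± 0.04. DNA replication genes fell in 33 of 43 and rose in 3, 34 and 4 adjusted over the list alone. The median was -0.29 (camera adjusted p = 8.1e-08, adjusted p = 0.0040 with an estimated correlation). Histone genes rose in 22 of 28 and fell in 1, 23 and 2 adjusted over the list alone. The median was 0.84 (camera adjusted p = 2.1e-05, adjusted p = 0.0082 with an estimated correlation). AXIN2 rose from 8.11 to 49.2 CPM, LEF1 rose by 1.43 ± 0.06, from 30.2 to 81.7 CPM, and CTNNB1 fell by 0.40 ± 0.03. IGFL2 rose from 0.0386 to 31.5 CPM (9.44 ± 0.33) and the cytoskeletal gene LIMCH1 fell from 283 to 10.4 CPM (-4.76 ± 0.05). p53 targets rose in 18 of 30 and fell in 4, 19 and 5 adjusted over the list alone. The median was 0.32 (camera adjusted p = 0.011, adjusted p = 0.016 with an estimated correlation). The death receptor gene FAS was at 1.05 ± 0.08. Wnt targets rose in 18 of 29 and fell in 5, 18 and 6 adjusted over the list alone. The median was 0.59 (camera adjusted p = 0.0073, adjusted p = 0.19 with an estimated correlation). RNF43 was at 3.62 ± 0.23. In all, 12004 genes passed the threshold, 6428 up and 5576 down, 1804 and 620 of them at least 2-fold, and 1245 passed the test against a 2-fold change.

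CHIR in dhelix FOXP2 cells, against dhelix FOXP2 alone, lowered all 35 mitotic genes, the same adjusted over the list alone. The median was -0.80 (camera adjusted p = 2.3e-24, adjusted p = 0.016 with an estimated correlation). DNA replication genes fell in 30 of 43 and rose in 8, 30 and 9 adjusted over the list alone. The median was -0.21 (camera adjusted p = 0.00015, adjusted p = 0.032 with an estimated correlation). AXIN2 rose by 2.65 ± 0.10, from 9.99 to 62.4 CPM, and LEF1 by 1.51 ± 0.06, and CTNNB1 fell by 0.16 ± 0.03, or by 0.25 with no filter on low counts. Wnt targets rose in 19 of 29 and fell in 5, the same adjusted over the list alone. The median was 0.48 (camera adjusted p = 0.0012, adjusted p = 0.075 with an estimated correlation). TNFRSF19 was at 3.46 ± 0.21. IGFL2 rose from 0.0418 to 47.2 CPM (10.08 ± 0.29, or 10.91 without dhelix replicate 5), and the long noncoding RNA LINC00473 (-5.11 ± 0.29) and SLAMF9 (-4.41 ± 0.15) fell. In all, 11680 genes passed the threshold, 6310 up and 5370 down, 1580 and 608 of them at least 2-fold, and 1140 passed the test against a 2-fold change. CHIR effects in mock and in WT FOXP2 cells, which share no library, had the same direction for 6301 calls and the opposite for 2997. Independent lists would share 2493 of the 3367 that rose in both and 1969 of the 2934 that fell in both, and hold 2163 and 2269 in the opposite directions against 1596 and 1401 here. For mock and dhelix FOXP2 cells the calls were 6253 and 2860 (2447 of the 3421 that rose in both and 1896 of the 2832 that fell in both from independent lists).

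The interaction of WT FOXP2 with CHIR asks for which genes the effect of the WT FOXP2 plasmid differed once CHIR was present. CHIR went with 2.17 times the FOXP2 level in WT FOXP2 cells. A response altered by CHIR therefore cannot be told apart from a response to more FOXP2. LMCD1, a LIM-domain gene, went from 170 to 20.3 CPM with WT FOXP2 without CHIR and from 12.6 to 34.3 CPM with it (interaction 4.49 ± 0.08), and the clock-related repressor gene BHLHE41 from 146 to 8.51 CPM and from 10.8 to 13.6 CPM (4.43 ± 0.08). SLAMF7, a lymphocyte receptor gene, rose from 4.04 to 58.6 CPM without CHIR and went from 95.2 to 70.1 CPM with it (-4.29 ± 0.07), and MGAT5 had an interaction of -2.66 ± 0.05. The AXIN2 interaction did not pass (-0.19 ± 0.14, adjusted p = 0.25), whereas CTNNB1 (0.13 ± 0.04, adjusted p = 0.0037) and LEF1 (-0.22 ± 0.08, adjusted p = 0.015) did. The FOXP2 effect was more positive with CHIR for 24 of 28 histone genes and less so for 1, the same adjusted over the list alone. The median was 1.40 (camera adjusted p = 2.5e-06, adjusted p = 0.0069 with an estimated correlation). It was more positive for 31 of 42 extracellular matrix genes and more negative for 6, the same adjusted over the list alone. The median was 0.97 (camera adjusted p = 4.3e-07, adjusted p = 0.24 with an estimated correlation). CHIR replicate 1, which enters this contrast, had its matrix list at -0.28 against the 4 other CHIR libraries (these at -0.05 to 0.14). The FOXP2 effect was more negative for 78 of 83 ribosomal protein genes and more positive for 1, 79 and 1 adjusted over the list alone. The median was -0.47 (camera adjusted p = 1.5e-14, adjusted p = 0.24 with an estimated correlation). In all, 12130 genes passed, 5677 positive and 6453 negative, of which 2764 and 1252 were at least 2-fold, and 2318 passed the test against a 2-fold change. The LEF1 call was lost without mock replicate 1, WT replicate 2, or WT + CHIR replicate 1 or 5, where its adjusted p was at most 0.078, and with a mean of at least 1 CPM required (adjusted p = 0.11, the highest over its alternatives). The CTNNB1 call was lost with no filter on low counts (adjusted p = 0.13, the highest over its alternatives).

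The interaction of dhelix FOXP2 with CHIR had LMCD1 at 4.07 ± 0.07, the matricellular gene SMOC1 at 5.26 ± 0.10, THBS1 at 2.19 ± 0.05, SLAMF7 at -4.28 ± 0.07 and the actin-binding gene LIMA1 at -2.88 ± 0.07. With CHIR the FOXP2 level in dhelix FOXP2 cells was 2.54 times that without, which cannot be told apart from the drug here either. CTNNB1 passed (0.38 ± 0.04), and AXIN2 (-0.14 ± 0.13, adjusted p = 0.36) and LEF1 (-0.15 ± 0.08, adjusted p = 0.099) did not. Extracellular matrix genes were more positive in 36 of 42 and more negative in 5, the same adjusted over the list alone. The median was 1.04 (camera adjusted p = 2.9e-09, adjusted p = 0.12 with an estimated correlation). CHIR replicate 1, with its matrix list at -0.28 against the 4 other CHIR libraries, enters this contrast too. Ribosomal protein genes were more negative in 80 of 83 and more positive in 1, the same adjusted over the list alone. The median was -0.56 (camera adjusted p = 9e-19, adjusted p = 0.12 with an estimated correlation). In all, 11987 genes passed, 5762 positive and 6225 negative, of which 2649 and 1211 were at least 2-fold, and 2207 passed the test against a 2-fold change. LEF1 passed without dhelix replicate 1 (adjusted p = 0.031) or dhelix + CHIR replicate 1 (adjusted p = 0.032), and AXIN2 and LEF1 passed with no filter on low counts (adjusted p = 0.039 and 0.012, the lowest over the alternatives of each).

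The last comparison asks whether the difference between dhelix and WT FOXP2 itself changed with CHIR, and it gave the fewest calls of the 12 comparisons. The dhelix FOXP2 transcript was at 0.751 times WT without CHIR and 0.881 times with it, so the FOXP2 level is part of this contrast. The difference was more positive with CHIR for THBS1 (0.81 ± 0.05), TRAF1 (1.08 ± 0.07), IL8 (1.15 ± 0.09), the dynein motor gene DYNC1H1 (0.46 ± 0.04) and HEG1 (0.55 ± 0.05), and more negative for MLC1 (-1.03 ± 0.09), MAL (-1.29 ± 0.12), MUC5AC (-1.44 ± 0.13) and the hearing-related myosin gene MYO7A (-1.07 ± 0.11). MUC5AC, for example, was at 40.2 against 5.14 CPM without CHIR and at 151 against 53.1 CPM with it. Histone genes were more negative in 8 of 28 and more positive in 0, 11 and 0 adjusted over the list alone. The median was -0.29 (camera adjusted p = 5.3e-07, adjusted p = 0.0012 with an estimated correlation). In dhelix replicate 5, the library with much noncoding RNA, the histone list lay at 0.12 against the 4 other dhelix libraries (these at -0.12 to 0.01). Axon guidance genes were more positive in 11 of 40 and more negative in 1, 13 and 1 adjusted over the list alone. The median was 0.22 (camera adjusted p = 9.9e-05, adjusted p = 0.00082 with an estimated correlation). SEMA3A was at 0.84 ± 0.14. Genes described as FOXP2 targets were more positive in 7 of 19 and more negative in 0, 8 and 0 adjusted over the list alone. The median was 0.22 (camera adjusted p = 0.0010, adjusted p = 0.0046 with an estimated correlation). VLDLR was at 0.40 ± 0.07. Cytokine genes were more positive in 7 of 21 and more negative in 0, 10 and 0 adjusted over the list alone. The median was 0.21 (camera adjusted p = 0.00012, adjusted p = 0.041 with an estimated correlation). AXIN2 (0.04 ± 0.15, adjusted p = 0.89) and LEF1 (0.07 ± 0.08, adjusted p = 0.61) did not pass, and CTNNB1 did (0.24 ± 0.04), although not with no filter on low counts (adjusted p = 0.056, the highest over its alternatives). In all, 2627 genes passed, 1650 positive and 977 negative, of which 57 and 123 were at least 2-fold, while 0 passed edgeR's test against a 2-fold change. At an unadjusted p under 0.05 there were 5011 genes, and DESeq2 called 2751. The share of positive calls was 62.8%, against 30.4% with no filter on low counts, 51.5% with a mean of at least 1 CPM, 50.3% without the 3 libraries that stood apart and 52.6% in a fit of these 4 groups alone.

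**Figure D2:**
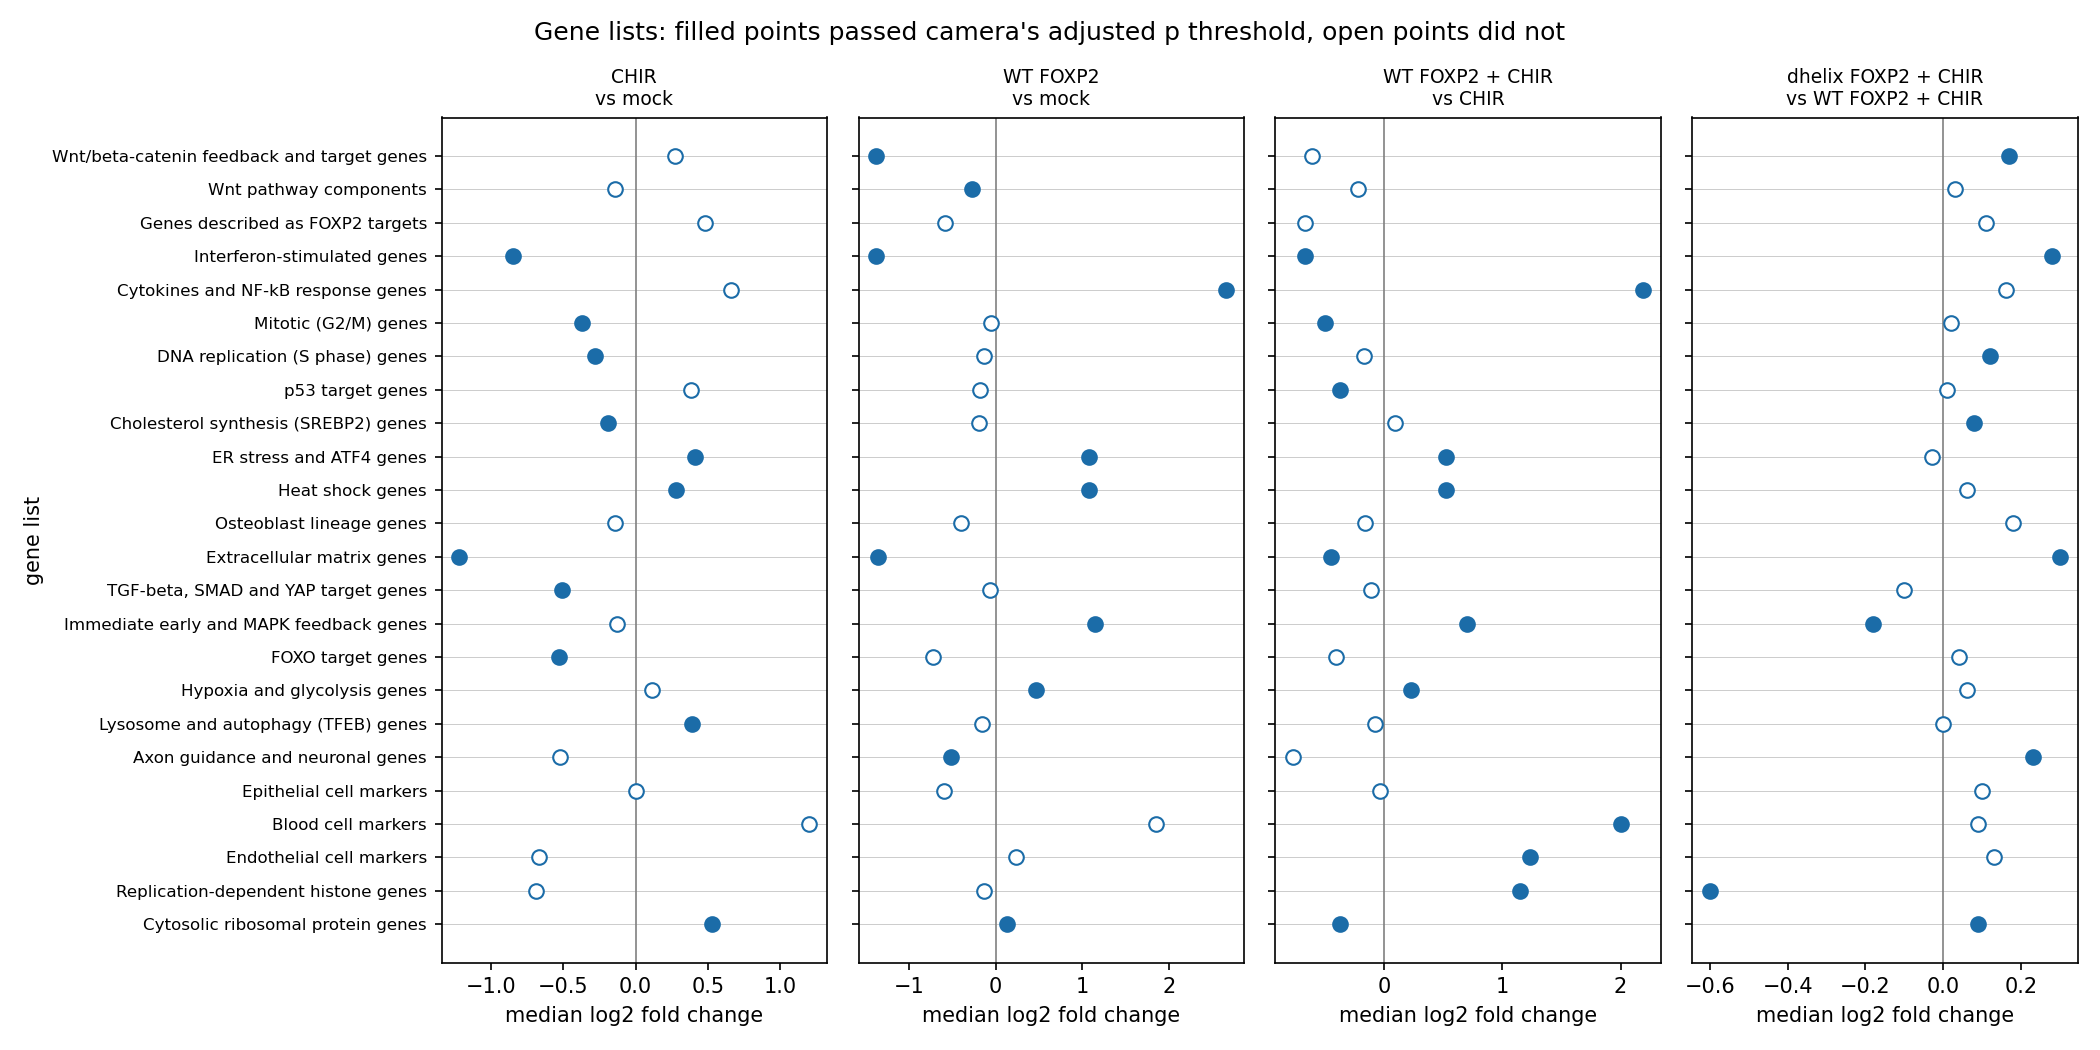
Median log2 fold change of the members of each gene list (horizontal axis) in 4 comparisons (CHIR against mock, WT FOXP2 against mock, WT FOXP2 + CHIR against CHIR, and dhelix against WT FOXP2 with CHIR); filled points passed camera's adjusted p threshold and open points did not. Cytokine genes lie at 2.66 with WT FOXP2 and at 2.19 with WT FOXP2 and CHIR, and extracellular matrix genes lie at -1.22 with CHIR.

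**Figure D3:**
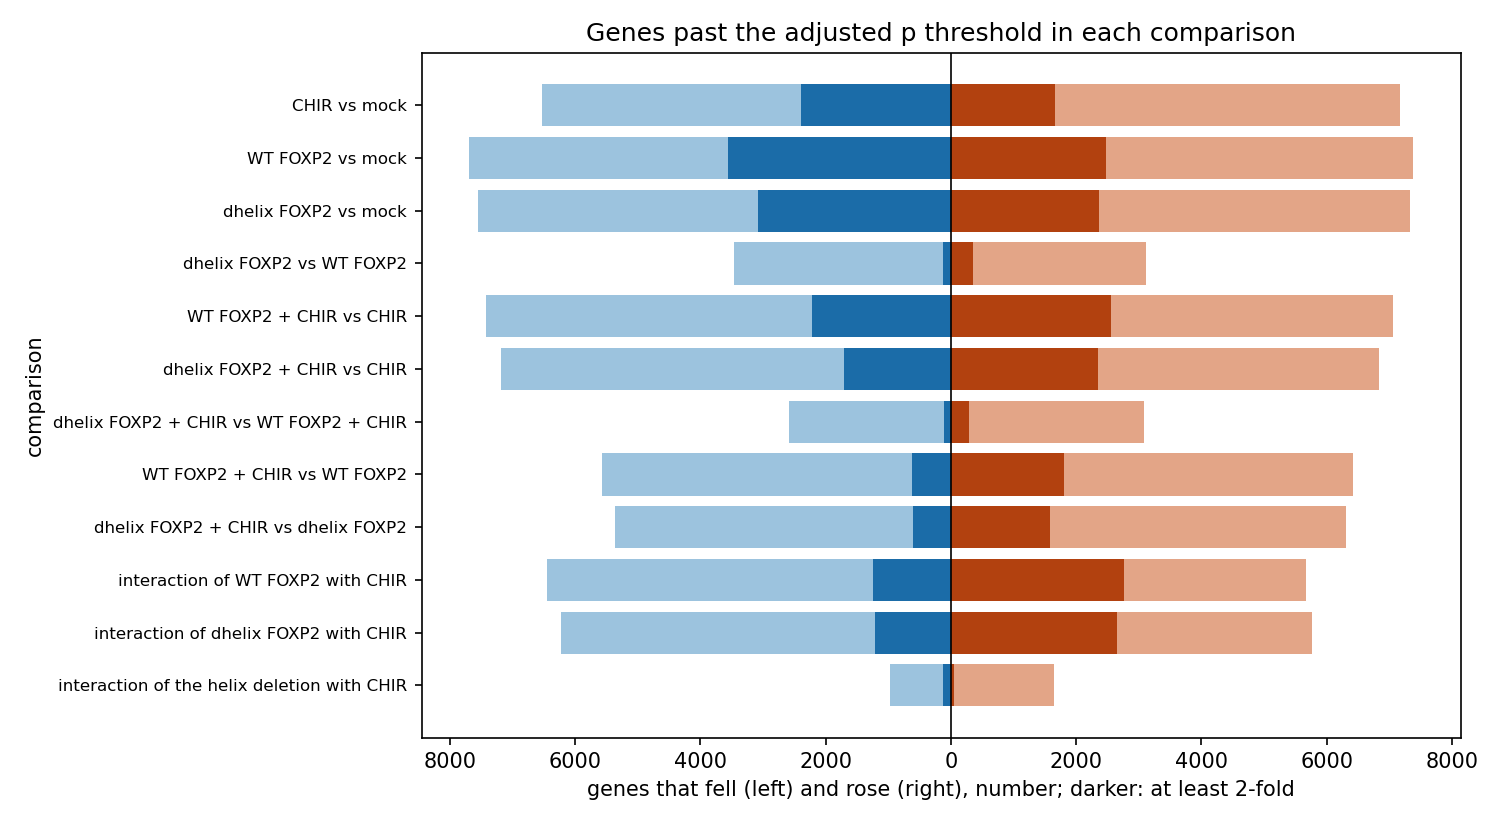
Number of genes past the adjusted p threshold in each comparison, those that rose to the right of 0 and those that fell to the left; the darker part changed at least 2-fold. WT FOXP2 against mock has the most calls, 7384 and 7699, and the interaction of the helix deletion with CHIR the fewest, 1650 and 977.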

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

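In this part the splits of the libraries and the tests of the shared mock libraries, of a floor of few counts and of a lower FOXP2 level were chosen only after the results were seen, and the splits for interactions and the tests of the floor and of a lower FOXP2 level were revised, with other genes or baselines, once a first result was known.

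CHIR went with 2.17 times the FOXP2 level in WT FOXP2 cells and 2.54 times in dhelix FOXP2 cells. The interaction test therefore cannot tell a response altered by CHIR from a response to more FOXP2. The effect of each FOXP2 construct differed with CHIR by the interaction test, for 12130 genes with WT FOXP2 and 11987 with dhelix FOXP2. With WT FOXP2 these included LMCD1 (4.49), BHLHE41 (4.43), SLAMF7 (-4.29), MGAT5 (-2.66), CTNNB1 (0.13) and LEF1 (-0.22, a call lost without mock replicate 1, WT replicate 2 or WT + CHIR replicate 1 or 5, adjusted p at most 0.078). With dhelix FOXP2 they included SMOC1 (5.26), LMCD1 (4.07), THBS1 (2.19), CTNNB1 (0.38), SLAMF7 (-4.28) and the actin-binding gene LIMA1 (-2.88). The helix deletion itself had an interaction with CHIR for 2627 genes: the cytokine genes IL8 (1.15) and TRAF1 (1.08), the guidance gene SEMA3A (0.84), THBS1 (0.81), HEG1 (0.55), DYNC1H1 (0.46), VLDLR (0.40), CTNNB1 (0.24), and on the other side MUC5AC (-1.44), MAL (-1.29), MYO7A (-1.07) and MLC1 (-1.03).

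The first pattern is that CHIR and WT FOXP2 moved many genes the same way against mock, and that together they fell short of the sum of their log2 fold changes: 4743 genes rose and 4732 fell with each (2863 and 2718 from independent lists), and 2248 went opposite ways. A sum on the log2 scale stands for a product of fold changes. For genes that rise, added amounts of transcript also fall short of that product. The shortfall there does not argue against added amounts, which were not tested. For genes at least 2-fold lower with each alone, added losses would leave no transcript. Their median with both was -2.21, so added amounts do not describe them. The 844 genes at least 2-fold higher with each alone had medians of 1.85 with CHIR, 2.07 with WT FOXP2 and 2.76 with both, where the sum has a median of 4.05, and the 1548 genes at least 2-fold lower had -1.77, -2.09 and -2.21, where the sum has -3.98. The correlation across genes of 0.51 hardly exceeds the 0.49 of simulated groups with no effect, but the shared mock libraries are argued against by a covariance of 0.987 that stayed at 0.988 or more over 10 splits of those libraries, against 0.0081 in the simulated groups. A floor of few counts cannot hold back the higher genes (median interaction -1.20 to -1.13 over 10 splits in which genes were picked in some libraries and measured in others) and is argued against by a median of at least 1.03 for the 390 to 503 lowered genes whose sum lay at 1 CPM or more, while for the 1000 to 1136 with a sum under 1 CPM (at least 1.89) it cannot be told apart from a shortfall of another kind. It stays open whether the mock libraries stand apart from the 5 other groups, which cannot be told apart from a response that both treatments evoke: with no mock library and no shared library, the WT FOXP2 effect with CHIR and the CHIR effect with dhelix FOXP2 correlated at 0.14 across genes, between the values set for either outcome, and such a response could also give this pattern and was not tested.

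The second pattern is the difference between dhelix and WT FOXP2, past the threshold for 6588 genes without CHIR. dhelix replicate 5, with much noncoding RNA, is argued against as the cause, since 6164 genes passed without it. Less FOXP2 transcript with dhelix FOXP2 was weighed by assuming that responses to the FOXP2 level have the same form with and without CHIR. That form may differ, since CHIR changed the WT FOXP2 effect for 12130 genes and went with 2.17 times the FOXP2 level in WT FOXP2 cells. For the 1826 genes that differed the same way in both backgrounds and lay nearer the control in both, less FOXP2 transcript is argued against as the whole cause only under that assumption. With such genes picked in 3 replicates of each group and measured in the other 2 (596 to 1903 genes, 10 splits), dhelix FOXP2 kept 66.2% ± 3.5 of the WT effect with CHIR, where its transcript was at 0.881 of WT, and 73.0% ± 2.5 without CHIR, where it was at 0.751 (medians over genes, mean and SD over n = 5), the former lower in all 10 splits, and on the wider set of 2837 genes with a WT effect of at least 2-fold in both backgrounds it kept 84.0% ± 3.2 and 90.3% ± 2.1 (two-sided exact permutation p = 0.0159, over the dhelix libraries alone). Without CHIR taken alone, the 73.0% kept is a share of a log2 effect, for genes picked as nearer the control. The 0.751 is a ratio of levels, so these values cannot be compared in size. That background by itself does not argue against the lower level. Beyond the WT effect in both backgrounds went 197 raised genes, MUC5AC and MAL among them, and 48 lowered ones (79 and 81 if all 4 lists were independent). The baseline first used, 160 from independent lists, left less transcript open as their cause, and the 48 lowered genes lay under their 81. It was then replaced by false calls, taken as independent between backgrounds, which give 2.5. Against that number, these 245 argue against less transcript as their cause if responses grow with the FOXP2 level. Responses that fall again at high levels, protein levels and a loss of contacts through the deleted residues may play a part and were not tested.

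Splits of the libraries into other groups of the same sizes, 100 per comparison with the real one among them, were tested with edgeR in fits of the compared groups alone. Chance is argued against for the 9 counts between pairs of groups, because in each only 1 of the 100 splits, the real one, gave a count as large. Mixed splits put the group difference into the spread, so they give few calls where groups differ. They cannot tell the treatment from another condition shared by all 5 libraries of a group. The real counts were 12181 for CHIR, 14571 for WT FOXP2 and 14991 for dhelix FOXP2 against mock, 8166 for dhelix against WT FOXP2, 12709 for WT FOXP2 + CHIR and 12007 for dhelix FOXP2 + CHIR against CHIR, 11979 for CHIR in WT FOXP2 cells and 12029 for CHIR in dhelix FOXP2 cells, each with 0 as the highest of the other splits, and 6695 for dhelix against WT FOXP2 with CHIR, with 10. For the 3 interactions such splits also break the effects of construct and CHIR, and the highest others called 7536 genes against the real 11621 with WT FOXP2, 10650 against 11552 with dhelix FOXP2, and 4037 against 4291 for the helix deletion. The splits with over 1 call, 1, 5 and 2 of them, kept or exchanged all 10 libraries of 1 CHIR level whole, so they follow the structure of the samples, a large construct effect within that level, and do not test the interaction. With both effects kept and only the residuals of log2 CPM redrawn over the libraries (limma, genes at 1 CPM or more in each group, 100 splits), the real order gave 9319 calls against at most 5385 with WT FOXP2, 9344 against 2988 with dhelix FOXP2 and 4239 against 336 for the helix deletion, so that chance is argued against there too. These residuals still hold the interaction, so the other splits are not free of it.

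Of 305 sets of 5 libraries examined, 26 (8.52%) held a library whose gap to the nearest other exceeded 0.71 of the range, Dixon's critical value, which chance exceeds in about 1 in 20 groups. Noncoding RNA was such a value in dhelix replicate 5 (share of the range 0.966), WT + CHIR replicate 4 (0.952) and mock replicate 2 (0.819), with RN7SL1 (0.935) and RN7SL2 (0.826) in dhelix replicate 5. The total count stood out in mock replicate 3 (0.732) and FOXP2 in CHIR replicate 4 (0.90), at 1.33 CPM against at most 0.357. CHIR replicate 1 stood out for TOP2A (0.803), TP53INP1 (0.783) and KANK4 (0.764). Genes with counts in 1 library of the group had a share of 1: HTR2A in WT replicate 2, LPAR6 in CHIR replicate 4, and MAL in mock replicate 2 and CHIR replicate 5. FOXS1 in CHIR replicate 5 was at 0.842. The other shares were 0.772 for GALNT15 in mock replicate 1, 0.802 for BMP2 in mock replicate 3, 0.743 for OASL in mock replicate 5, 0.711 for VLDLR in WT replicate 1, 0.807 for BHLHE41 in WT replicate 4, 0.741 for INSIG1 in dhelix replicate 2, 0.895 for NID1 in dhelix replicate 4, 0.72 for IL6 in WT + CHIR replicate 1, 0.716 for VLDLR and 0.755 for VWF in dhelix + CHIR replicate 2, and 0.752 for TRAF1 in dhelix + CHIR replicate 5.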

How the results depend on the processing

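The test against a 2-fold change and the fit without 3 libraries were chosen only after the results were seen. The 12 counts of genes past the threshold stayed within 1.5 times their values with DESeq2 size factors, with DESeq2, with no filter, with a mean of at least 1 CPM, with FOXP2 left out of library sizes, without the 3 libraries that stood apart and without any 1 library. In a fit of the compared groups alone 11 of the 12 did, and the interaction of the helix deletion with CHIR moved from 2627 to 4291 calls; the cause was not tested. Against a 2-fold change the counts dropped by construction, to 2828 for CHIR, 4670 for WT FOXP2 and 4123 for dhelix FOXP2 against mock, 3328 for WT FOXP2 and 2688 for dhelix FOXP2 with CHIR against CHIR, 75 and 23 for dhelix against WT FOXP2 without and with CHIR, 1245 and 1140 for CHIR in WT and dhelix FOXP2 cells, 2318 and 2207 for their interactions with CHIR, and 0 for the helix deletion (unadjusted p under 0.05 for 5011 genes, 2751 calls in DESeq2 without that fold threshold). Of the 24 gene lists in 12 comparisons, 41.3% of tests passed with the preset correlation, 9.03% with an estimated one, and 87.5% with fry, which tests a list by itself and not against other genes. No called list turned its direction under any of the 4 list alternatives. The 2 FOXP2 level comparisons and the 2 overlaps of WT and dhelix effects kept their side under every alternative run. Of 157 calls for named genes, each a gene in 1 comparison, 151 held in every alternative except the 2-fold test, 6 were lost in at least 1 of these, 3 of 9 genes without a call gained one, and none reversed; 111 passed the 2-fold test. Fixing the replicate block moved counts little (6649 against 6588 for dhelix against WT FOXP2, 2708 against 2627 for the helix interaction). By mean correlation, replicate numbers paired the libraries weakly: same-numbered libraries of different groups were at 0.0083, against -0.0021 for other numbers. Among 75 pairs 1 exceeded 0.1. In all, 12 of 30 libraries correlated best with their own number, and without the number expected by chance this does not exclude some pairing. The block brought FOXP2 in CHIR against mock past the threshold (adjusted p = 0.04; 0.0013 to 0.36 over all alternatives) and moved 3 list calls across it. Depth limits genes near 0 counts, where fold changes are bounds or ratios with wide intervals.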

Other observations

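In this part the test of S phase and the sum of abundant RNAs without a tail were chosen only after the result was seen, as was leaving out the 3 libraries that stood apart.

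The unfolded protein response gene DDIT3 (1.82 ± 0.05) and CHAC1, a glutathione-degrading enzyme gene (2.51 ± 0.10), rose with CHIR alone. Of 36 ER stress and ATF4 genes 21 rose and 12 fell, the same adjusted over the list alone (median 0.41, camera adjusted p = 0.028, adjusted p = 0.22 with an estimated correlation). Cholesterol synthesis genes went both ways with WT FOXP2: HMGCS1, an early enzyme gene of the pathway, rose from 129 to 624 CPM (2.28 ± 0.05), while SREBF2, which encodes the pathway's transcription factor, fell by 1.39 ± 0.05. In all, 6 of the 24 rose and 15 fell, 6 and 18 adjusted over the list alone (median -0.19, camera adjusted p = 0.23). INSIG1 rose with dhelix FOXP2 against mock (1.23 ± 0.06), and with WT FOXP2 + CHIR against CHIR (2.26 ± 0.06).

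Interferon-stimulated genes fell with WT FOXP2 + CHIR against CHIR in 23 of 31 cases and rose in 5, the same adjusted over the list alone (median -0.67, camera adjusted p = 0.0041, adjusted p = 0.20 with an estimated correlation). In WT FOXP2 + CHIR replicate 4 this list lay at a median of -0.13 against the 4 others of its group. TRIM22 fell by 2.35 ± 0.11, while OASL, which CHIR had lowered from 17.9 to 0.346 CPM, rose to 4.11 CPM (3.55 ± 0.17). For the helix deletion the interaction with CHIR was positive for 9 of these genes and negative for 1, 11 and 1 adjusted over the list alone (median 0.17, camera adjusted p = 0.0018, adjusted p = 0.21 with an estimated correlation). Lysosome and autophagy genes rose with CHIR in WT FOXP2 cells in 23 of 35 and fell in 6, the same adjusted over the list alone (median 0.23, camera adjusted p = 0.0026, adjusted p = 0.22 with an estimated correlation).

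The third pattern is that histone transcripts were higher with WT FOXP2 and CHIR than with dhelix FOXP2 and CHIR, by 1.09 times in sum (923 ± 22.1 against 844 ± 9.67 CPM, SD, n = 5) and by more per gene. Without the 3 libraries that stood apart, 20 of 28 histone genes were lower with dhelix FOXP2 (median -0.65, quartiles -0.98 and -0.35). Carry-over of RNA without a poly(A) tail cannot be told apart from a change in the histone transcripts themselves: 59 other RNAs without a tail, most of them small, had a median of -0.02 (quartiles -0.31 and 0.19), above the bound of -0.33 set for the test, but abundant ones (RN7SL1, RN7SL2, RN7SK, RMRP, RPPH1 and 2 ribosomal RNAs) were in sum at -0.35, past that bound. A larger share of cells in S phase with WT FOXP2 and CHIR is argued against only as far as transcripts of DNA replication genes follow that share. These genes were slightly higher with dhelix FOXP2 and CHIR (median 0.12, 24 of 43 higher and 3 lower). The share of cells itself was not measured. A change in how histone transcripts are processed or tailed may also play a part, as a hypothesis that gene counts cannot test.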
